A study of Mus musculus with 8 samples.

How the data were processed

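RNA sequencing libraries were made from macrophages sorted from 8 subcutaneous MC38 tumors, 4 in mice labelled Atg5 WT and 4 in mice labelled Atg5 KO. Per the labels' protocols, total RNA was extracted with a Zymo kit and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA, STAR and the mm10 genome, without versions or roles. The counting tool, its strand setting, the treatment of reads shared by several genes and the annotation release are not given in the sources used here.

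The authors deposited 1 table of FPKM values, fragments scaled by gene length and by the library's total, for 35275 genes, with gene names, coordinates and gene lengths. Of the gene identifiers, 34490 (97.8%) are in GENCODE release 21 for mouse. Every FPKM value multiplied by the gene's length was a whole multiple of 1 step per library (100% of values, within 0.01 fragments), which gave back the fragments per gene. Their totals were 21554368, 18563894, 19565420 and 14799546 in Atg5 WT mice 1 to 4 and 25555195, 16168331, 16759765 and 17652632 in the KO-labelled mice 1 to 4. The 10 most abundant genes took between 6.19% and 7.45% of the fragments. FPKM is scaled to the fragments assigned to genes in each library, so a rise of some genes lowers the values of the others. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 9.18 or more over genes), so all 8 were kept as separate samples.

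Columns were matched to samples by the name of each column, and groups and mouse numbers were taken from the labels. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, two-sided, for the 11019 genes with a mean FPKM of at least 1 over all 8 libraries, followed by Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. Adjusted p values of single genes are from limma unless another test is named. Gene lists were tested with camera from limma, with its preset correlation of 0.01 between genes, for lists with at least 5 kept members, with adjustment over the 32 lists tested. Camera compares a list with all other genes, so its direction can differ in sign from the list's mean or median. This was so for autophagy machinery, cell cycle and fatty acid oxidation, which had positive means and a downward direction, the median gene changing by 0.03. The immune checkpoint list had a median of -0.0033 with an upward direction, and the complement list a mean of -0.00065 with a median of 0.011. List means per library were compared by exact permutation over all assignments of 4 against 4, for which the smallest p is 0.0286, and adjusted over the same lists. The lists, the tests and the alternatives were fixed before the data were examined, except those said to have been added.

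Mouse numbers are shared by the groups, and it was checked whether same-numbered libraries deviate together from their group means. The correlations over genes were 0.841, 0.208, 0.458 and 0.471 for mice 1 to 4, each above 0.1, so the numbers were taken to pair the libraries and a fit with the mouse number as a block was set beside the main one. The pairing comes from this check and not from the labels, which name separate mice. Among mice 2 to 4 alone the correlations were 0.297, -0.134 and 0.205, so much of the pairing comes from mouse 1. Deviations from a group mean cancel within the group, so the mouse 1 shift alone raises the correlations of the other mice. The best match in the other group had the same number for 2 Atg5 WT and 3 KO-labelled libraries. Pairs are therefore not established for mice 2 to 4.

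Genes named in the text were always Atg5 and Lyz2, then genes past the threshold with separate groups or, where fewer than 5 passed in a direction, the 6 with the smallest p in that direction, leaving out pseudogenes and names of unnamed gene models. From each list that passed or is described, up to 4 members with the smallest p were taken. Genes used to describe the mouse 1 libraries and the neighbours of Atg5 were chosen after their values were seen.

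The tests were checked on simulated fragments drawn for the real genes and depths with 200 genes changed, 198 of which the filter kept. For this comparison with 10777 genes tested and no shift shared by the mouse 1 libraries, the main test recovered 80.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 11 false among 195 calls. With the shift of the mouse 1 libraries kept and 10946 genes tested, it recovered 14.9%, 67.2% and 98.4%, with 0 false among 118 calls. The block recovered 76.1%, 98.5% and 100%, with 12 false among 193 calls, and had 17 false among 199 without the shift. Both mouse 1 libraries were given the same shift, which the block removes by construction. The changed genes were drawn from the better covered genes only. The simulated genes shared 1 smooth trend of spread, so the real genes can be noisier. In each simulation camera called the shifted list and 0 of 30 unchanged lists. The simulated genes were drawn independently and the unchanged lists held random genes. The estimated correlation between members of the real lists ran from -0.03 to 0.80, so the simulation does not check camera on correlated lists.

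The alternatives set beforehand were pseudocounts of 0.1 and 0.5, filters at a mean FPKM of 0.1 and 5 and none, TPM, median-of-ratios and quantile scaling, no trend, robust variances, array weights, the mouse number as a block, a minimum log2 change of 1, each library left out, and for lists an estimated correlation and the fry test. Added after seeing the data were a term for mouse 1 against mice 2 to 4, both mouse 1 libraries left out, voom on the recovered fragments with and without the block, centring in 20 bins of GC content with the block, an estimated correlation with the block, and the macrophage identity list without Lyz2. GC content came from the longest GENCODE transcript of each gene and was known for 99.6% of the kept genes. The median GC content of genes higher or lower by over 1 in mouse 1 was compared with 10000 random gene sets of the same size. Values per exon or transcript were not analysed here.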

Results

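Gene expression was measured by RNA sequencing in tumor-associated macrophages from mouse MC38 tumors, and the comparison asked which genes differ when the myeloid cells of the host carry a deletion of Atg5, a gene needed to form autophagosomes. MC38 is a mouse colon adenocarcinoma cell line. Female C57BL/6J mice of 6 to 8 weeks received 100000 MC38 cells under the skin, and tumors were taken at day 21. Cells that were CD11b+ F4/80+ Ly6G- Ly6C- were sorted from each tumor, so that the gate removed Ly6G+ neutrophils and Ly6C+ monocytes. There were 8 libraries, 4 labelled Atg5 WT (floxed Atg5 without Cre) and 4 labelled Atg5 KO (floxed Atg5 with LysMcre, a Cre recombinase placed in the Lyz2 gene). The libraries came from separate mice, numbered 1 to 4 in each group. The deposited values were FPKM for 35275 genes. Fragments assigned to genes, recovered from the FPKM values and the gene lengths, numbered 21554368, 18563894, 19565420 and 14799546 in Atg5 WT mice 1 to 4 and 25555195, 16168331, 16759765 and 17652632 in the libraries labelled Atg5 KO, mice 1 to 4.

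Atg5 RNA was not lower in the libraries labelled Atg5 KO. Atg5 (ENSMUSG00000038160, chromosome 10, 44268358 to 44364291 on the plus strand of mm10) had an FPKM of 4.52 ± 1.49 (SD, n = 4) in the Atg5 WT libraries and 14.03 ± 1.51 (SD, n = 4) in the libraries labelled Atg5 KO, 3.1 times as high. The single values were 6.73, 3.50, 3.93 and 3.91 in Atg5 WT mice 1 to 4 and 16.20, 13.83, 12.81 and 13.27 in the KO-labelled mice 1 to 4. Between 136 and 974 fragments lay behind each value. The difference was 1.48 ± 0.17 (SE) on the log2(FPKM + 1) scale, with an adjusted p of 0.0987 in limma. With the mouse number as a block the adjusted p was 0.00481, without both mouse 1 libraries it was 0.0024, and without Atg5 WT replicate 1 alone it was 0.00155. The exact permutation p was 0.0286, two-sided, the smallest that 4 against 4 allows. Since the targeted gene went against its label, the second group is called the libraries labelled Atg5 KO throughout, and each direction below rests on that label. The FPKM of the whole gene includes exons outside the floxed part, so it does not check the deletion itself, and values per exon were not used here.

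Lyz2, the lysozyme gene whose locus carries the Cre, had lower values in every library labelled Atg5 KO. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277334 to 117282274, minus strand) had an FPKM of 5249 ± 825.5 (SD, n = 4) in Atg5 WT and 3022 ± 310.6 (SD, n = 4) in the KO-labelled libraries. Its log2 difference was -0.79 ± 0.13 (SE) and did not pass the limma threshold (adjusted p = 0.985). The exact permutation p was again 0.0286. Lyz1, the neighbouring paralog at 117287796 to 117292868, had 35.57 ± 14.59 FPKM (SD, n = 4) in Atg5 WT and 118.5 ± 28.41 (SD, n = 4) in the KO-labelled libraries, with an adjusted p of 0.999. Lyz1 and Lyz2 are similar in sequence and how shared reads were counted is not given in the sources used here, so the Lyz1 value is uncertain.

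**Figure D1:**
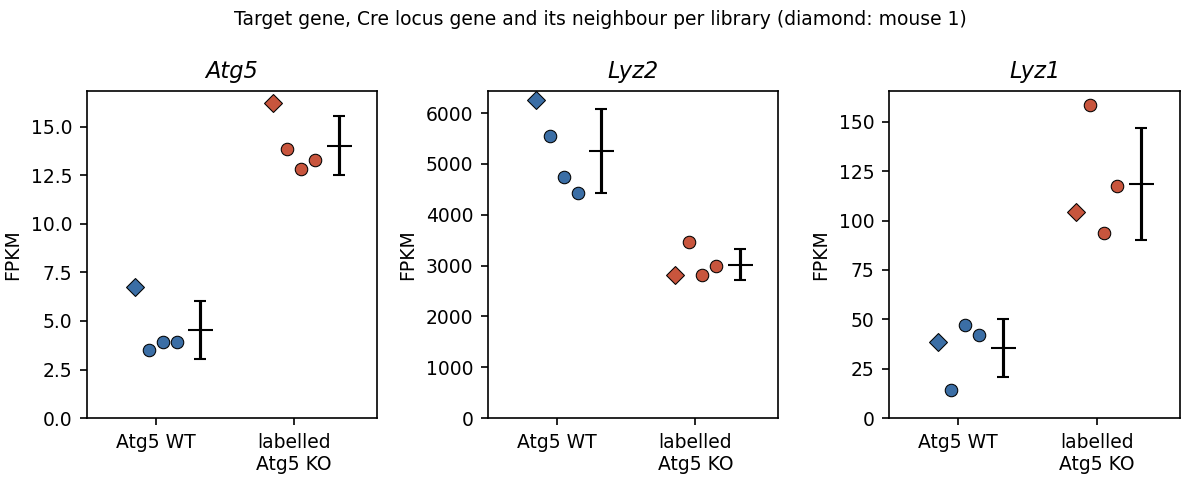
FPKM of Atg5, Lyz2 and Lyz1 on linear axes from 0, with 1 point per library (diamonds for mouse 1) and the mean ± SD of the 4 libraries of each group in black. All 4 KO-labelled libraries lie above the Atg5 WT libraries for Atg5 (12.81 to 16.20 against 3.50 to 6.73) and Lyz1, and below them for Lyz2 (2808 to 3467 against 4436 to 6268).

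Across all genes, no gene passed an adjusted p of 0.05 in limma among the 11019 genes with a mean FPKM of at least 1. At an unadjusted p under 0.05 there were 223 genes, 132 with higher and 91 with lower values in the KO-labelled libraries. An even spread of p values would give about 551, and the shared mouse 1 difference described below widens the spread within groups in this test. The balance of directions depended on scaling, with 107 higher and 141 lower under median-of-ratios scaling and 188 and 69 with TPM. With the mouse number as a block, 1 gene passed, Atg5, and 971 genes had an unadjusted p under 0.05. Limma's voom on the recovered fragments also called 1 gene, Atg5, and 4 genes with the block.

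None of the genes with the smallest p values passed in the main test. Atg5 passed with the block and in some other settings, and Lyz2 only with voom and the block (adjusted p = 0.0495). On the higher side after Atg5 and Lyz1 came Fpr1, Rnf128, Fpr2 and Saa3, in that order. Fpr1 and Fpr2 are receptors for formylated peptides. Fpr1 had 2.48 ± 0.47 FPKM (SD, n = 4) in Atg5 WT and 5.72 ± 1.75 (SD, n = 4) in the KO-labelled libraries, and Fpr2 had 9.80 ± 1.15 and 18.88 ± 4.95. Rnf128, a ubiquitin ligase, stood at 9.98 ± 0.54 and 14.82 ± 1.75. Saa3, an acute-phase protein, stood at 4.89 ± 1.05 and 10.67 ± 3.39. On the lower side after Lyz2 came Lag3, an immune checkpoint receptor, with 4.88 ± 0.80 FPKM in Atg5 WT and 2.49 ± 0.62 in the KO-labelled libraries. Cd2, an adhesion molecule of lymphocytes, had 3.04 ± 0.69 and 1.51 ± 0.28, from 22 to 90 fragments per library. Tlr12 had 5.21 ± 0.59 and 3.36 ± 0.48. Folr2, a folate receptor of tissue macrophages, had 42.38 ± 5.64 and 28.21 ± 5.16, and Sertad1 had 69.24 ± 4.45 and 51.50 ± 6.12. Each of these 9 genes lay on the same side in all 4 pairs of same-numbered mice, and each had an adjusted p of 0.999. All but Saa3 had groups that did not overlap, so any pairing of the mice would give the same count.

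The mouse 1 libraries of both groups stood apart from the other 6 libraries. The first principal component held 58.94% of the variance and placed Atg5 WT mouse 1 at -34.72 and KO-labelled mouse 1 at -37.78, with the other 6 between -3.71 and 21.34. KO-labelled mouse 2 stood apart on the second component (18.34% of the variance), at 29.34 against -15.01 to 3.42 for the other libraries. Of 15 fibroblast markers, 8 were higher in both mouse 1 libraries than in all 6 others. The mean FPKM of the markers was 9.75 in WT mouse 1 and 18.9 in KO-labelled mouse 1, and 1.64 to 3.46 in the other 6 libraries. Col3a1, a fibrillar collagen, reached 74.1 and 149 FPKM in the mouse 1 libraries against 10.2 ± 3.59 (SD, n = 6) elsewhere. Col1a1 did not follow, with 4.37 and 10.4 FPKM in the mouse 1 libraries of Atg5 WT and of the KO-labelled group against 7.52 ± 1.21 (SD, n = 6). Among the macrophage markers, Csf1r was at 364 and 363 FPKM in the mouse 1 libraries and 380 ± 17.3 (SD, n = 6) elsewhere.

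**Figure D2:**
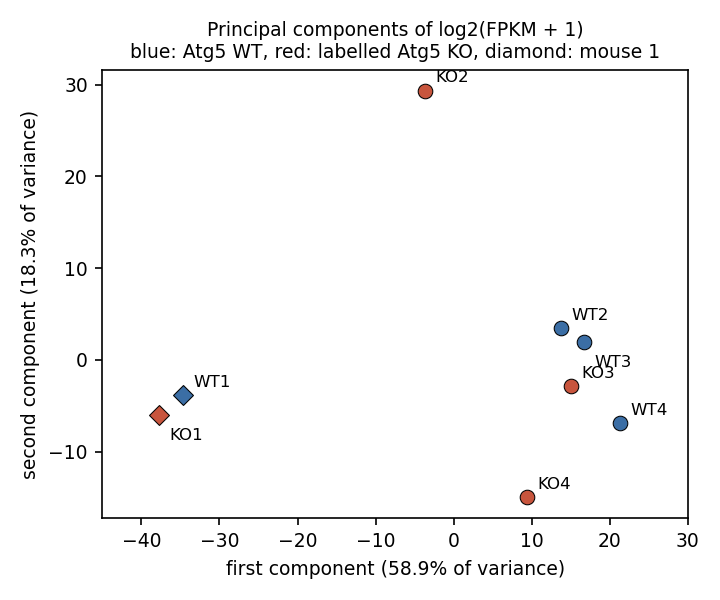
First principal component (horizontal, 58.94% of variance) against the second (vertical, 18.34%) of log2(FPKM + 1) over 11019 genes, with 1 point per library. The mouse 1 libraries of both groups (diamonds) lie at -34.72 and -37.78 on the first component, away from the other 6.

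Among the 40 gene lists fixed before the data were examined, 32 had at least 5 measured members and were tested with camera. Of these, 14 passed, 5 higher and 9 lower in the KO-labelled libraries, 10 of them pathways and 4 of them cell type markers. No list passed with an estimated correlation between genes in place of the preset 0.01. The fry test called none (smallest adjusted p = 0.125). By exact permutation of the list means no list passed after adjustment over the 32 lists, the smallest adjusted p being 0.731. The smallest p this test allows is 0.0286, so a pass would have needed many lists at that floor together. The failure therefore says little about any single list. Without the mouse 1 libraries of both groups, 9 of the 14 still passed. The count of calls was 7 without Atg5 WT replicate 1 and 9 without KO-labelled replicate 1. With the block all 14 passed, and so did the neutrophil list.

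**Figure D3:**
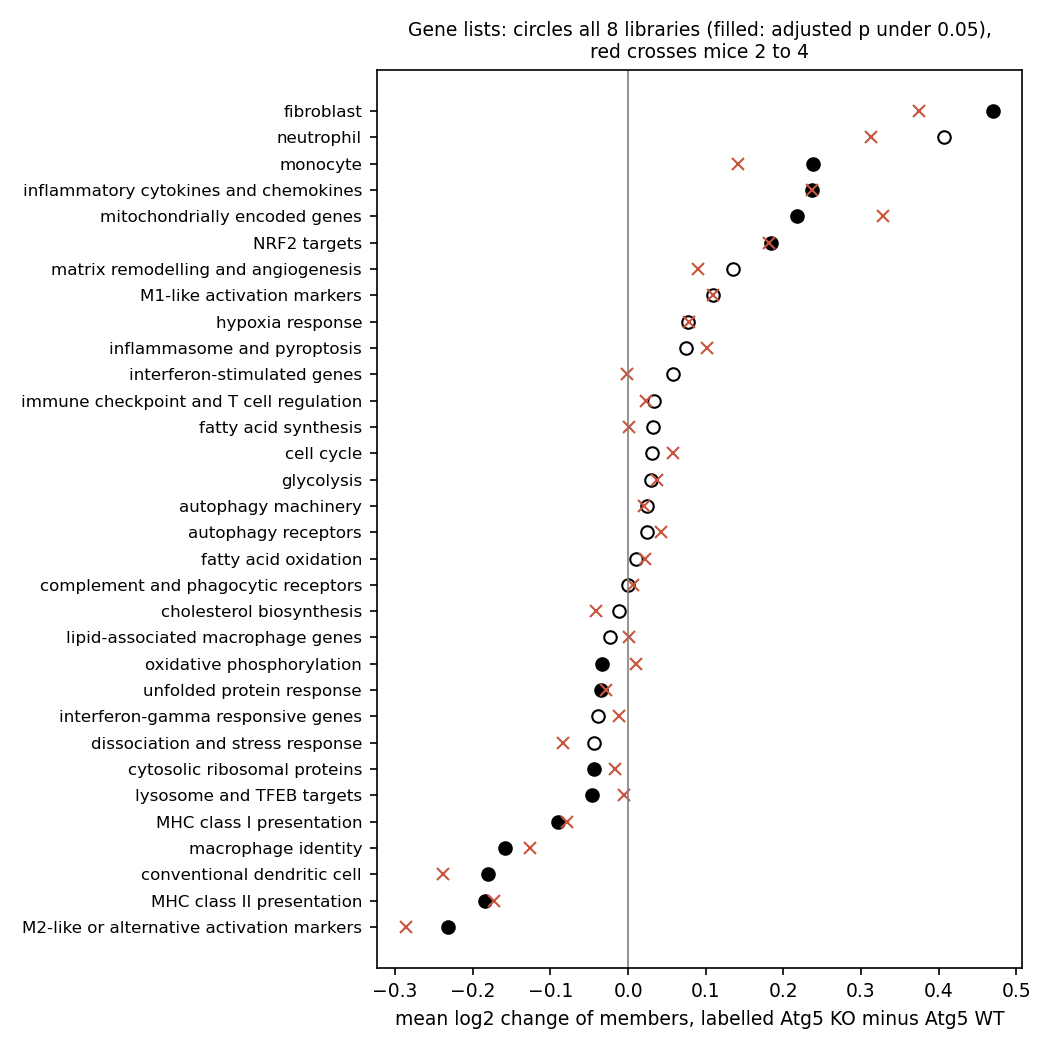
Mean log2(FPKM + 1) change of the members of the 32 tested lists, KO-labelled minus Atg5 WT, over all 8 libraries (circles, filled where the camera adjusted p was under 0.05) and over mice 2 to 4 (red crosses). The M2-like list lies lowest at -0.23 and the fibroblast list highest at 0.47.

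The MHC class II, MHC class I and conventional dendritic cell lists were called lower in the KO-labelled libraries with the preset correlation, but not with an estimated one. The MHC class II list fell by 0.18 on the log2 scale over 16 members (camera adjusted p = 1.14e-05, and adjusted p = 0.371 with an estimated correlation). Of its members, 4 were lower and 1 higher at an unadjusted p under 0.05, and none passed when adjusted over the list alone. With the block, 5 members lower and 1 higher passed when adjusted over the list alone. The list mean was 7.59 ± 0.07 (SD, n = 4) in Atg5 WT and 7.40 ± 0.17 (SD, n = 4) in the KO-labelled libraries, lower in 3 of 4 pairs. Cd74, the invariant chain, had 7846 ± 363.9 FPKM in Atg5 WT and 6102 ± 685.5 in the KO-labelled libraries. H2-Eb1, a class II chain, had 4639 ± 293.0 and 3547 ± 565.4, and Ifi30, a lysosomal thiol reductase, had 874.5 ± 18.72 and 716.8 ± 97.07. March1, a ubiquitin ligase that removes class II from the surface, went the other way, with 14.32 ± 1.64 and 17.66 ± 1.67. The MHC class I list fell by 0.09 over 23 members (adjusted p = 0.000579, and adjusted p = 0.46 with an estimated correlation), with no member at an unadjusted p under 0.05. H2-K1 had 1725 ± 187.6 and 1538 ± 190.4 FPKM, and the immunoproteasome subunit gene Psmb10 had 153.2 ± 13.90 and 132.6 ± 23.52. Its call was lost without KO-labelled replicate 1 (change -0.06, adjusted p = 0.0655) or 4 (-0.05, 0.0869). The conventional dendritic cell list fell by 0.18 over 12 members (adjusted p = 0.00163, and adjusted p = 0.46 with an estimated correlation), and its call was lost without the same libraries (-0.12 and -0.11, adjusted p = 0.051 and 0.0869). Over all fits without 1 library the change lay between -0.30 and -0.08. Batf3, a dendritic cell transcription factor, had 15.03 ± 2.78 and 9.81 ± 1.56 FPKM, and Mgl2, a lectin also on the M2-like list, had 260.9 ± 47.66 and 179.1 ± 38.01. Adjusted over the list alone, no member of these 2 lists passed in the main test, while with the block 2 members of the dendritic cell list passed, both lower, and none of the class I list.

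The M2-like and macrophage identity lists were also called lower with the preset correlation, but not with an estimated one. The M2-like list, markers of alternative activation, fell by 0.23 over 27 members, 22 of which had negative changes, and its mean was lower in all 4 pairs (adjusted p = 1.42e-05, and adjusted p = 0.164 with an estimated correlation). The mean FPKM of the members did not fall, at 155 in Atg5 WT and 158 in the KO-labelled libraries. Of the 27 members, 10 were also on other lists. Folr2 and Mgl2 were the only M2-like members at an unadjusted p under 0.05, and none passed when adjusted over the list alone (1 with the block, lower). With the block, 2 members were higher and 5 lower at an unadjusted p under 0.05. Msr1, a scavenger receptor, had 151.7 ± 23.77 FPKM in Atg5 WT and 185.5 ± 22.87 in the KO-labelled libraries. The macrophage identity list fell by 0.16 over 19 members (adjusted p = 0.000579, and adjusted p = 0.431 with an estimated correlation). C1qa, a complement subunit, had 2102 ± 210.0 and 1590 ± 390.4 FPKM, whereas Itgam, which encodes the CD11b used in the sort, had 254.1 ± 11 and 322.6 ± 24.98. In the main test only Lyz2 passed when adjusted over the list alone, and with the block 5 members lower and 1 higher did. With Lyz2 removed, since its locus carries the Cre, the list fell by 0.12 with an adjusted p of 0.00975. The call of the full list was lost without KO-labelled replicate 1 (change -0.10, adjusted p = 0.0986).

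NRF2 targets, genes of the oxidative stress response, were higher in the KO-labelled libraries by a mean of 0.18 over 21 members (adjusted p = 0.000158, and adjusted p = 0.101 with an estimated correlation). Changes were positive for 17 members, 4 of them at an unadjusted p under 0.05, and none passed when adjusted over the list alone (5 with the block, all higher). The list mean was 6.02 ± 0.05 (SD, n = 4) in Atg5 WT and 6.21 ± 0.08 (SD, n = 4) in the KO-labelled libraries, higher in all 4 pairs. The exact permutation p was 0.0286, the smallest possible. After adjustment over the 32 lists it was 0.731, an adjustment that a single list cannot pass. Gclm, a subunit of the enzyme that limits glutathione synthesis, had 5.12 ± 0.16 and 7.10 ± 0.98 FPKM. Gsr, glutathione reductase, had 21.01 ± 5.15 and 31.17 ± 6.11, Srxn1, sulfiredoxin, had 21.62 ± 1.70 and 29.39 ± 5.90, and the transporter gene Abcc1 had 22.91 ± 3.56 and 30.64 ± 5.16. The call was lost without Atg5 WT replicate 1 (change 0.17, adjusted p = 0.0815). Inflammatory cytokine and chemokine genes rose by 0.24 over 32 members (adjusted p = 0.000579, and adjusted p = 0.476 with an estimated correlation), with 7 members higher and 1 lower at an unadjusted p under 0.05. None passed when adjusted over the list alone, while 7 higher and 1 lower did with the block. Il1a had 29.84 ± 1.5 and 60.23 ± 32.58 FPKM, Il6 had 5.61 ± 1.21 and 12.94 ± 8.43, and Cxcl2, a neutrophil chemokine, had 760.5 ± 92.89 and 1118 ± 331.9. KO-labelled mouse 2 held the highest value of all 3, and without it the list changed by 0.11 and was no longer called (adjusted p = 0.196). With array weights the change was 0.12 (adjusted p = 0.249). Without Atg5 WT replicate 1 the change was 0.25, but the list was not called either (adjusted p = 0.0684).

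**Figure D4:**
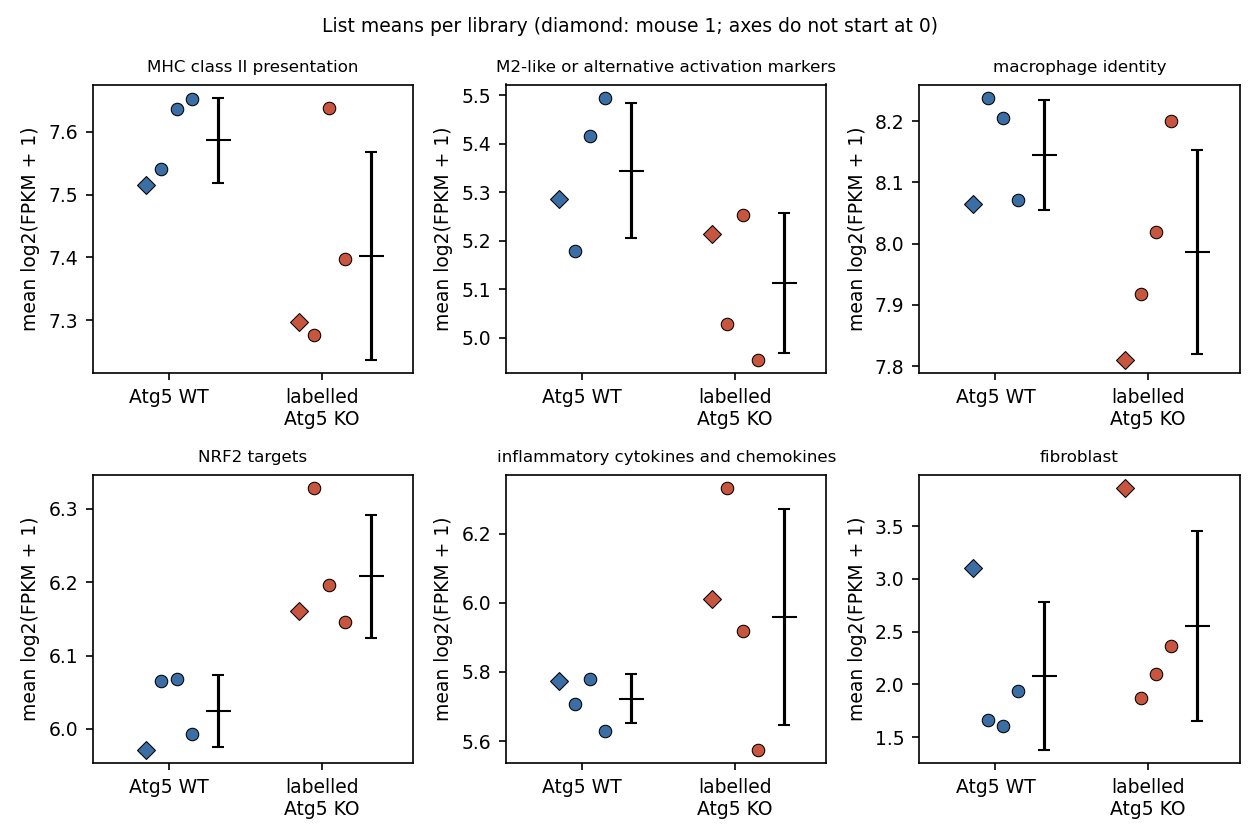
Mean log2(FPKM + 1) of the members of 6 lists, with 1 point per library (diamonds for mouse 1) and the mean ± SD of each group in black; the axes do not start at 0. The ranges of the NRF2 list do not overlap (5.97 to 6.07 against 6.15 to 6.33). Its exact permutation p was 0.0286, the smallest possible, and 0.731 after adjustment, which a single list cannot pass. The other 5 overlap, and the fibroblast list is highest in both mouse 1 libraries (3.11 and 3.86).

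The monocyte and fibroblast marker lists were called higher in the KO-labelled libraries with the preset correlation, but not with an estimated one. The monocyte list rose by 0.24 over 13 members (adjusted p = 0.0127, and adjusted p = 0.431 with an estimated correlation). The change was 0.53 within mouse 1 and 0.14 over mice 2 to 4, where the list did not pass (adjusted p = 0.158). Without KO-labelled replicate 1 the change was 0.10 (adjusted p = 0.0871), without KO-labelled replicate 3 it was 0.20 (0.12), and without Atg5 WT replicate 1 it was 0.28 (0.152). F13a1, a coagulation factor of monocytes, had 58.69 ± 13.86 and 93.99 ± 24.20 FPKM. The fibroblast list rose by 0.47 over 9 members, all with positive changes (adjusted p = 0.0149, and adjusted p = 0.632 with an estimated correlation) and had its highest means in the mouse 1 libraries. The change was 0.76 within mouse 1 and 0.38 over mice 2 to 4 (adjusted p = 0.000144). Without KO-labelled replicate 1 the change was 0.06 (adjusted p = 0.426), and without Atg5 WT replicate 1 it was 0.81 (adjusted p = 0.0177). Without Atg5 WT replicate 2 or 3 it was 0.33 and 0.31 (0.0603 and 0.0616). Col1a1 had 6.21 ± 1.71 and 8.75 ± 1.11 FPKM. Adjusted over the list alone, no member of either list passed in the main test, while with the block 2 monocyte and 6 fibroblast markers passed, all higher.

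The remaining calls were small or moved with single libraries. Lysosome and TFEB target genes fell by 0.05 over 42 members (adjusted p = 0.00137, and adjusted p = 0.431 with an estimated correlation), with Ctsa, a lysosomal protease, at 210.7 ± 11.62 and 176.0 ± 24.77 FPKM. Over mice 2 to 4 the change was -0.0057 and the adjusted p 0.16, and the call was also lost without Atg5 WT replicate 1 (change -0.03, 0.0684), without KO-labelled replicate 1 (-0.02, 0.0987) and with quantile normalization (0.0938). Cytosolic ribosomal protein genes fell by 0.04 (adjusted p = 0.00607, and adjusted p = 0.763 with an estimated correlation). Unfolded protein response genes fell by 0.04 (adjusted p = 0.0149, and adjusted p = 0.632 with an estimated correlation), Herpud1 having 51.19 ± 5.87 and 41.59 ± 6.35 FPKM. Nuclear oxidative phosphorylation genes fell by 0.03 (adjusted p = 0.0235, and adjusted p = 0.697 with an estimated correlation). None of these 3 passed over mice 2 to 4, with adjusted p values of 0.49, 0.104 and 0.872. Mitochondrially encoded genes rose by 0.22 over 12 members (adjusted p = 0.0392, and adjusted p = 0.763 with an estimated correlation), with a change of 0.33 over mice 2 to 4 (adjusted p = 5.07e-05) and -0.11 within mouse 1. The ribosomal call was lost without Atg5 WT replicate 1 (change -0.01, adjusted p = 0.257), KO-labelled replicate 1 (-0.05, 0.0871) or KO-labelled replicate 2, where the mean turned positive (0.02, 0.728). It was also lost with quantile normalization (0.684) and GC centring with the block (0.0522). The oxidative phosphorylation call was lost without the same 3 libraries (changes -0.014, -0.0098 and -0.011, adjusted p = 0.266, 0.81 and 0.135), with filters at 0.1 (0.0757) or none (0.146), with quantile normalization (0.234) and with TPM (0.0856). Its mean was positive over mice 2 to 4 (0.0101) and with TPM (0.0027). The unfolded protein response call was lost without Atg5 WT replicate 1 (0.255) or KO-labelled replicate 3 (0.135), where the mean turned positive (0.0093 and 0.0007). It was also lost without Atg5 WT replicate 2 (-0.02, 0.132) or KO-labelled replicate 4 (-0.01, 0.183), with filters at 0.1 (0.0757) or none (0.0875) and with quantile normalization (0.131). The mitochondrial call was lost without Atg5 WT replicate 2, 3 or 4 (changes 0.10, 0.14 and 0.14, adjusted p = 0.293, 0.196 and 0.195) and without KO-labelled replicate 1 or 2 (0.05 and 0.20, 0.469 and 0.243). It was lost too with a pseudocount of 0.1 (0.0549), filters at 0.1 (0.0771) or none (0.0778) and TPM (0.102). Over all fits without 1 library the change of the mitochondrial list lay between 0.05 and 0.49. With array weights the ribosomal and oxidative phosphorylation means were positive (0.030 and 0.032, both adjusted p = 0.819).

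Neither list of autophagy genes passed. The autophagy machinery list, which leaves Atg5 out, had a mean change of 0.03 over 41 members (adjusted p = 0.979), and the autophagy receptor list had 0.03 over 16 members (adjusted p = 0.979). Atg10, which encodes the enzyme that joins ATG12 to ATG5, had 3.37 ± 1.00 and 4.66 ± 0.74 FPKM and was the only machinery gene at an unadjusted p under 0.05. Bnip3, a mitophagy receptor, had 89.67 ± 20.98 and 102.8 ± 7.13. The interferon-stimulated list (adjusted p = 0.476), the interferon-gamma list (0.0796), the M1-like list (0.548) and the lipid-associated macrophage list (0.151) did not pass either. Within these, Nos2 had 87.66 ± 20.58 and 134.9 ± 55.63 FPKM, Cd274, which encodes PD-L1, had 62.23 ± 1.91 and 80.13 ± 22.39, and Gpnmb had 13.04 ± 2.82 and 9.01 ± 0.43.

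Genes close to the 2 engineered loci were counted at an unadjusted p under 0.05, since no gene passed anywhere in the main test. The window of 10 Mb around Atg5 on chromosome 10 was counted as 48 kept genes, with 10971 in the comparison set. The window around Lyz2 was counted as 62, with 10957. These make up all kept genes, so Atg5 and Lyz2, each with such a p, were not left out of the test. Lyz1, whose value is uncertain, lies in the Lyz2 window and also had such a p. Each window held 2 genes with such a p (two-sided Fisher's exact test against all other kept genes, p = 0.254 and 0.358).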

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

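The tests of swapped labels, of mouse 1 as the source of the Atg5 difference, of other cell types, of GC content for the MHC class II list and for the genes higher or lower in mouse 1, and of stromal cells were chosen after the results had been seen. Within each group of 4 libraries, a library far from the other 3 was looked for in 216 sets of values, and 15 were found, where chance gives about 10.8. In 13 of the 15 the library was mouse 1.

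In the Atg5 WT group, mouse 1 stood apart for Atg5 (gap to range ratio 0.831), Cxcl2 (0.85), Col3a1 (0.854), mt-Nd4 (0.955), mt-Co1 (0.965), mt-Nd1 (0.841), Bnip3 (0.933), Stmn1 (0.888), the mean of the mitochondrially encoded genes (0.901) and the first principal component (0.865). Among the KO-labelled libraries, mouse 1 stood apart for Col1a2 (0.943), Col3a1 (0.883) and the number of fragments (0.842, with 25555195). The other 2 were Tlr12 in Atg5 WT mouse 3 (0.887, 6.09 FPKM) and Bst2 in KO-labelled mouse 2 (0.889, 145.3 FPKM).

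Atg5 RNA was 3.1 times as high in the libraries labelled Atg5 KO. A swap of the labels would place the lower Lyz2 values, expected where Cre disrupts 1 allele or both, in the Atg5 WT libraries, but the highest KO-labelled Lyz2 value was 0.782 times the lowest Atg5 WT value, which argues against it. Mouse 1 is not the source, since Atg5 passed without both mouse 1 libraries (adjusted p = 0.0024). A change of the whole region would raise the neighbours too, whereas the other kept genes within 1 Mb had a median log2 change of 0.0946 against 1.48 ± 0.17 (SE) for Atg5. A higher level of the remaining transcript in cells with the deletion may be the reason and stays open as an untested hypothesis, because values per exon were not used here.

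Lower MHC class II and macrophage lists with a higher monocyte list may reflect the Atg5 label, the makeup of the sorted cells, or chance. GC content is not the whole source for MHC class II. Its change went from -0.18 to -0.20 after centring in GC bins with the block (camera adjusted p = 1.89e-06). The range over all alternatives with the preset correlation was 1.27e-08 to 0.00693. No single library carried the whole change, which was -0.26 to -0.14 without 1 library (highest adjusted p = 0.000951). These p values rest on the preset correlation, and with an estimated one the list did not pass (adjusted p = 0.371). KO-labelled mouse 3 had a list mean of 7.64, inside the Atg5 WT range of 7.52 to 7.65. A larger share of every other cell type would raise all their markers, yet the conventional dendritic cell list had a mean change of -0.18. That decides nothing, because neither it (adjusted p = 0.46) nor the monocyte list (adjusted p = 0.431) passed with an estimated correlation, so the makeup of the sort cannot be told apart from a change within macrophages. Chance cannot be excluded for the number of lists, since 8 of the 35 splits of the 8 libraries into 4 and 4 called at least the real 14, the highest other split calling 22 (Atg5 WT mice 1 and 4 with KO-labelled mice 1 and 4), and among the 8 splits that part all 4 pairs, 3 did, the highest other calling 15.

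The mouse 1 libraries of both groups stood apart from the other 6, and 44.4% of genes had both mouse 1 values on 1 side of all others. Chance gives 7.14% for a pair of libraries named beforehand. The mouse 1 pair was singled out from these same values, so the share of 44.4% is a description and not a test. Depth is not the source, since thinning all libraries to the smallest depth left both at 1 end of a first component with 58.2% of the variance. GC content is a candidate source of the shift over all genes, with a Spearman correlation of -0.64 across genes, which are not independent. GC content is also a candidate for the genes lower by over 1 (median GC 59.7% against 49.7% for all genes). The 244 genes higher by over 1, taken as a set, go against it. Their median GC of 51.3% lay above the range of 95% of random sets (48.5 to 50.8). A set median cannot exclude GC content as a source for part of them. Stromal cells are a candidate source for part of the genes that were higher, with 8 of 15 fibroblast markers above all 6 other libraries in both, led by Col3a1 (74.1 and 149 FPKM), although Col1a1 did not follow (4.37 and 10.4 FPKM against 7.52 ± 1.21, SD, n = 6) and the CD11b+ F4/80+ sort would remove such cells. They are not the source of the genes that were lower, such as Cebpb (340 and 329 FPKM against 869 ± 254, SD, n = 6), since the macrophage identity list shifted by a median of -0.152; the labels name nothing that mouse 1 of both groups shares beyond its number, so no biological difference named by the design was tested.

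With 0 genes passing in the main limma test, 35 of the 35 splits reach that count by necessity (highest other 0), so the splits say nothing about it. At an unadjusted p under 0.05 the real split gave 223 genes and the highest other 3712, in a split with both mouse 1 libraries on 1 side. Such splits gave 1910 to 3712 genes with KO-labelled mouse 2 on that side and 191 to 1235 without it. This points to a structure of the samples that is not mouse 1 alone. A shift of KO-labelled mouse 2 lies in 1 group only, so neither the block nor the mouse 1 term removes it. Among the 8 splits that part all 4 pairs the real one gave the most, the next being 154. Pairs are not established for mice 2 to 4, however. Among splits that part only the mouse 1 libraries, Atg5 WT mice 1 to 3 with KO-labelled mouse 2 gave 401 genes. The real split therefore does not stand out once the mouse 1 libraries are parted.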

How the results depend on the processing

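Alternatives with mouse 1 as a term or left out, voom, GC centring and the estimated correlation with the block were added after seeing the data; the cause of each change below was not tested. With 0 genes called by the main limma test, median-of-ratios scaling, quantile normalization, array weights, the replicate block, the mouse 1 term, leaving out both mouse 1 libraries and voom each called 1 gene, Atg5, the 1 higher and 0 lower. GC centring with the replicate block called 2 (Atg5 and Col3a1), both higher, and voom with the replicate block called 4, with 3 higher (Atg5, Col3a1, Vcan) and 1 lower (Lyz2). Leaving out 1 library gave 0 to 1 genes, the 1 being Atg5 without Atg5 WT replicate 1, with 0 to 1 higher and 0 lower.

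Atg5 had log2 changes of 1.45 with median-of-ratios scaling (adjusted p = 0.0324), 1.43 with quantile normalization (0.0286), 1.55 with array weights (9.79e-05), 1.475 with the replicate block (0.00481), 1.475 with the mouse 1 term (0.00105), 1.58 without both mouse 1 libraries (0.0024), 1.62 with voom (0.0422), 1.61 with voom and block (0.00393) and 1.38 with GC centring and block (0.00258). Without 1 library it was 1.39 to 1.65, with adjusted p of 0.687 to 0.00155. Lyz2 passed only with voom and block (-0.82, adjusted p = 0.0495), and lay between -0.87 and -0.70 without 1 library. Col3a1 reversed to -0.024 without KO-labelled replicate 1 and reached 1.63 without Atg5 WT replicate 1.

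Of the 14 lists, 9 passed without both mouse 1 libraries, 0 with an estimated correlation, 0 with that and the block, and 0 with fry. Without 1 library, 7 to 16 of all 32 tested lists passed, lists outside the 14 included. The block added the neutrophil list (adjusted p = 0.0191) and changed no other list call. MHC class II and M2-like lists passed in all 23 refits with the preset correlation. With array weights the ribosomal and oxidative phosphorylation lists reversed, with means of 0.030 and 0.032 (both adjusted p = 0.819). Without losing the downward direction against all other genes, means also turned positive for the ribosomal list without KO-labelled replicate 2 (0.0206), oxidative phosphorylation without both mouse 1 libraries (0.0101) and with TPM (0.0027), and the unfolded protein response without Atg5 WT replicate 1 (0.0093) and KO-labelled replicate 3 (0.0007). Over lists and alternatives with the preset correlation, the call was kept in 270 cases, lost with its direction kept in 51 and lost with it reversed in 2. Of 223 genes at an unadjusted p under 0.05, 132 were higher, against 188 of 257 with TPM and 107 of 248 with median-of-ratios scaling. Depth limits genes such as Cd2, with 22 to 90 fragments per library.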

Other observations

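Neutrophil genes stood next to the threshold, in a sort that removes Ly6G+ cells. The neutrophil list had a mean change of 0.41 over 8 kept members of 21 (camera adjusted p = 0.0598, 0.0191 with the block, and adjusted p = 0.431 with an estimated correlation), and 0.31 over mice 2 to 4 (adjusted p = 0.688). S100a8, a calcium-binding alarmin, had 2.58 ± 1.34 FPKM (SD, n = 4) in Atg5 WT and 6.08 ± 3.41 (SD, n = 4) in the KO-labelled libraries, and Mmp8, a neutrophil collagenase, had 2.57 ± 0.69 and 5.55 ± 3.69. S100a8 was highest in mouse 1 of each group (4.14 and 10.18) and rested on 7 to 102 fragments per library. In KO-labelled mouse 4 S100a8 was at 2.02 FPKM, below the Atg5 WT mean. Mmp8 was highest in KO-labelled mouse 2 (11.02 FPKM), with 3.29 to 4.57 in the other KO-labelled libraries. Il1r2, a decoy receptor, had 102.0 ± 17.73 and 88.02 ± 17.36.

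Markers of other cell types were mostly low. Fewer than 5 members reached a mean FPKM of 1 for plasmacytoid dendritic cells (3), T cells (2), NK cells (2), B or plasma cells (3), mast cells or basophils (2), MC38 or epithelial tumor cells (4), endothelial cells (4) and erythroid cells or platelets (1), so these were not tested. The mean FPKM of the tumor cell markers was 2.35 to 4.76 over the 8 libraries. B or plasma cell markers reached 9.09 in Atg5 WT mouse 1 and 0.985 to 2.93 in the others. Among the called marker lists, other lists also held 9 of the 19 kept macrophage, 4 of the 13 monocyte, 5 of the 12 dendritic cell and 2 of the 9 fibroblast members.

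Further lists that did not pass were inflammasome and pyroptosis (adjusted p = 0.137), dissociation and stress response (0.274), hypoxia response (0.284), cholesterol biosynthesis (0.284), immune checkpoint and T cell regulation (0.678), complement and phagocytic receptors (0.697), glycolysis (0.883), and fatty acid synthesis, fatty acid oxidation, matrix remodelling and cell cycle (0.901 each). Genes whose groups did not overlap numbered 127 higher and 65 lower, 192 in all or 1.74% of 11019. Exchangeable libraries would give 2.86%, but the shared mouse 1 difference lowers that share, and the 7 other splits that part all 4 pairs gave 49 to 124 genes (0.445% to 1.13%). Pairs are not established for mice 2 to 4. A split that parts the mouse 1 libraries but not every pair gave 286 genes (Atg5 WT mice 1 to 3 with KO-labelled mouse 2). The real count is therefore not the highest once the mouse 1 libraries are parted. Prdm1, a transcription factor gene next to Atg5 on chromosome 10 (44437177 to 44528501), had a log2 change of 0.31, named after its value was seen.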
